A study of Mus musculus with 2 samples.

How the data were processed

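PolyA-plus RNA-seq was measured in 2 pools of mouse hindbrain (strain B6NCrl, embryonic day 12.5, mixed sex), pool 1 from 120 and pool 2 from 88 embryos. Per the labels' protocols, RNA was extracted with mirVana, 10 ng entered each library, cDNA was primed with oligo-dT, fragments were made by Nextera tagmentation, ERCC spike-in RNAs were added, and the manual of a SMARTer ultra low input kit is given. Amplification from low input and tagmentation can affect the recovery of long and of non-polyadenylated transcripts, and no molecular identifiers are mentioned, so intervals and floors cover counting error only. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty.

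Each pool had a gene table and a transcript table for each of 2 annotations, GENCODE M21 and GENCODE M4, on mm10, per the deposited read-me files. The program that made them is not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript that need not be whole and are not scaled for depth. The deposited TPM values sum to the same total over all entries, spike-ins and tRNA entries included, so a larger spike-in share lowers the TPM of every gene. The deposited FPKM values are per kilobase of effective length and per library total, per the file headers. The deposited isoform values in percent give each transcript's part of its gene; shares reported here were computed from transcript TPM. Effective length was feature length minus 99 bases for the features tested, and TPM recomputed from expected counts and effective lengths differed from the deposited TPM by a median of 0.00561% in pool 1 and 0.00565% in pool 2.

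The design was fixed at the same time as the alternatives listed at the end: M21, the newer annotation, was the main quantification, together with 31 gene lists, 8 pairs of lists and the rule for named genes. Genes excluded spike-ins and 26248 tRNA entries. Gene symbols matched 55450 of 55536 M21 gene identifiers; Ahsp, fixed in the erythroid list, matched none, and 12 of 13 members of that list were measured. Coordinates are those of GENCODE M21. The named genes are all Hox genes, the 4 members of highest mean TPM of every other list and up to 3 members under 1 TPM in both pools, the 10 genes of highest TPM, the 6 of largest ratio in each direction between the pools (mean TPM of 10 or more, 50 or more mean counts), the 5 of largest fold in each direction between annotations, and the 5 list genes of highest TPM whose top isoform held under 60% or differed between the pools. Genes of the lists added after the data were seen are named outside this rule, and some genes that the rule names are not reported here.

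Library totals on M21 were 32547454 expected counts in pool 1 and 30559015 in pool 2, spike-ins included. A gene with no count could hold up to 3 counts, which was converted to TPM with its own effective length. Lists were compared by the mean of log2(TPM + 0.1) per gene over the pools, with two-sided permutation tests across genes (100000 resamples, or exact where a list had under 10 members) and Benjamini-Hochberg adjustment over the 8 pairs; a log2 difference on this scale understates the change of low genes. Genes are not replicates, so these p-values describe the lists in these libraries. List medians were set against 10000 random lists, matched on mean expression in 20 bins for shifts between the pools. For levels, these lists were not matched. They were drawn from genes at 1 TPM or more in at least 1 pool and all protein-coding genes, expressed or not.

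Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave the common dispersion with an intercept-only design, TMM scaling and its default low-count filter (18575 genes). Ratios between the pools used TMM-scaled counts with a prior count of 0.5 and had no test, because the pools are the 2 replicates of 1 group. DESeq2 1.42.0 size factors, total counts and spike-in totals were alternative scalings. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

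The steps were tested on simulated data. For pool 2 against pool 1, with a true coefficient of variation of 0.1 and no gene changed, 0.0995 was recovered over 18803 genes; with 200 genes changed, 0.131 was recovered over 18775 genes, as changed genes enter an intercept-only fit. In the latter, 47% of genes changed 2-fold, 99% of those changed 4-fold and 0.0270% of unchanged genes passed the 2-fold limit. With a true coefficient of variation of 0.2, 0.198 was recovered over 18682 genes with no gene changed and 0.215 over 18636 genes with 200 changed, and 2.20% and 2.01% of unchanged genes passed the limit; with 200 changed, 51% of genes changed 2-fold and 97% of those changed 4-fold did. Of simulated list pairs without a difference, 1.67% passed the 0.05 threshold of the permutation test, and every pair simulated with a difference of 4 on the log2 scale did. Most differences reported below are smaller than 4, and how often the test finds such differences is not given by this simulation.

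Alternatives fixed before the data were examined were the M4 tables, posterior mean estimates, FPKM, other TPM thresholds, another pseudocount, count filters, other scalings and each pool alone. Chosen after the data were seen were TPM rescaled without spike-ins, low values set at the level of 3 counts, the prior count of 0.5, the use of list members with any count in the shifts, the 10 TPM limit for isoform shares, the separate muscle members, the histone genes and the 4 added lists. Alignments and signal tracks were not used here.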

Results

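Gene expression was measured in the hindbrain of B6NCrl mouse embryos at embryonic day 12.5. At this stage the hindbrain holds dividing progenitors of the ventricular zone beside newly formed neurons of the brainstem and cerebellum. The series holds 1 group of 2 biological replicates of mixed sex: pool 1 (replicate 1) was made from 120 embryos and pool 2 (replicate 2) from 88 embryos. The main gene quantification held 31469575 expected counts on genes in pool 1 and 29261472 in pool 2. With no second group there was no contrast between conditions. The comparisons below set gene lists against each other within the hindbrain, the 2 pools against each other, and the 2 deposited annotations against each other. Values are length-normalised transcript abundances (TPM) given as mean ± SD over the 2 pools (n = 2) unless a pool is named.

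In both pools, 16100 genes reached 1 TPM or more, of which 13619 were protein coding and 374 were lincRNAs. Protein-coding genes took 95.1% ± 0.403 of the gene counts (SD, n = 2). Among the 10 genes with the highest mean TPM were the cytoskeletal genes Actb (11943 ± 1128 TPM) and Tuba1a, a neuronal alpha-tubulin (7416 ± 32.4 TPM). The embryonic globin gene Hbb-y stood at 7248 ± 1260 TPM and the adult-type globin gene Hba-a2 at 5501 ± 768 TPM. The nuclear RNA Malat1 was at 6960 ± 620 TPM, and the mitochondrial genes mt-Atp8 and mt-Atp6 were at 4826 ± 6.92 and 4775 ± 621 TPM. The remaining 3 of these 10 genes were the signal recognition particle RNAs Rn7s1 and Rn7s2 and the ribosomal RNA entry CT010467.1, which are transcripts without a poly(A) tail. Rn7s1 and Rn7s2 are near-identical copies with the same estimate (8029 ± 1833 TPM each), so how their reads divide between them is uncertain, and the same holds for Hba-a2 and its copy Hba-a1.

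Hox genes, which encode the positional code of the hindbrain and spinal cord, were expressed up to paralog group 8 and were near 0 beyond it. Of paralog groups 1 to 4, 11 of 12 members reached 1 TPM in both pools, with Hoxd3 at 59.0 ± 7.21 TPM, Hoxb2 at 50.9 ± 8.24 TPM and Hoxa2 at 47.1 ± 9.46 TPM. The exception was Hoxb1, a gene of rhombomere 4 in the early hindbrain, at 1.74 TPM in pool 1 and 0.63 TPM in pool 2. The annotated Hoxd3 and Hoxd4 genes overlap on the same strand. So do Hoxa3 with Hoxa4, Hoxa5 and Hoxa6, and Hoxc5 with Hoxc6, Hoxc8, Hoxc9 and Hoxc10. How reads divide within each of these sets is uncertain. Of paralog groups 5 to 8, 8 of 11 members reached 1 TPM in both pools. Hoxb5 had the highest mean of the Hox genes (77.1 ± 27.6 TPM), and Hoxa5 (52.5 ± 15.8 TPM) and Hoxb6 (48.0 ± 2.76 TPM) followed within groups 5 to 8. Hoxa7, Hoxc8 and Hoxd8 were under 1 TPM in both pools.

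None of the 16 members of paralog groups 9 to 13 reached 1 TPM in either pool. Hoxb9 had the highest mean among them (0.320 ± 0.0566 TPM), and 9 members had no count in either pool, where 3 counts would correspond to at most 0.158 TPM (the value for Hoxa13). Hoxb5 (ENSMUSG00000038700.4, positions 96303336 to 96306121, plus strand) and Hoxb9 (ENSMUSG00000020875.9, positions 96271457 to 96276595, plus strand) both lie in the HoxB cluster on chromosome 11 of mm10. The mean of log2(TPM + 0.1) over groups 5 to 8 exceeded that over groups 9 to 13 by 5.43 ± 0.22 (SD, n = 2 pools). This gave an adjusted p of 8e-05 in a two-sided permutation test across genes, the smallest that the 100000 resamples can give after adjustment over 8 pairs of lists. With values under 3 counts set at the level of 3 counts, the difference was 4.81. Groups 1 to 4 exceeded groups 5 to 8 by 0.85 in the same measure, which was not past the threshold (permutation test, adjusted p = 0.442). That direction turned to -0.71 (adjusted p = 0.5, range over the alternatives 0.427 to 0.625) when members under 1 TPM in both pools were left out.

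**Figure D1:**
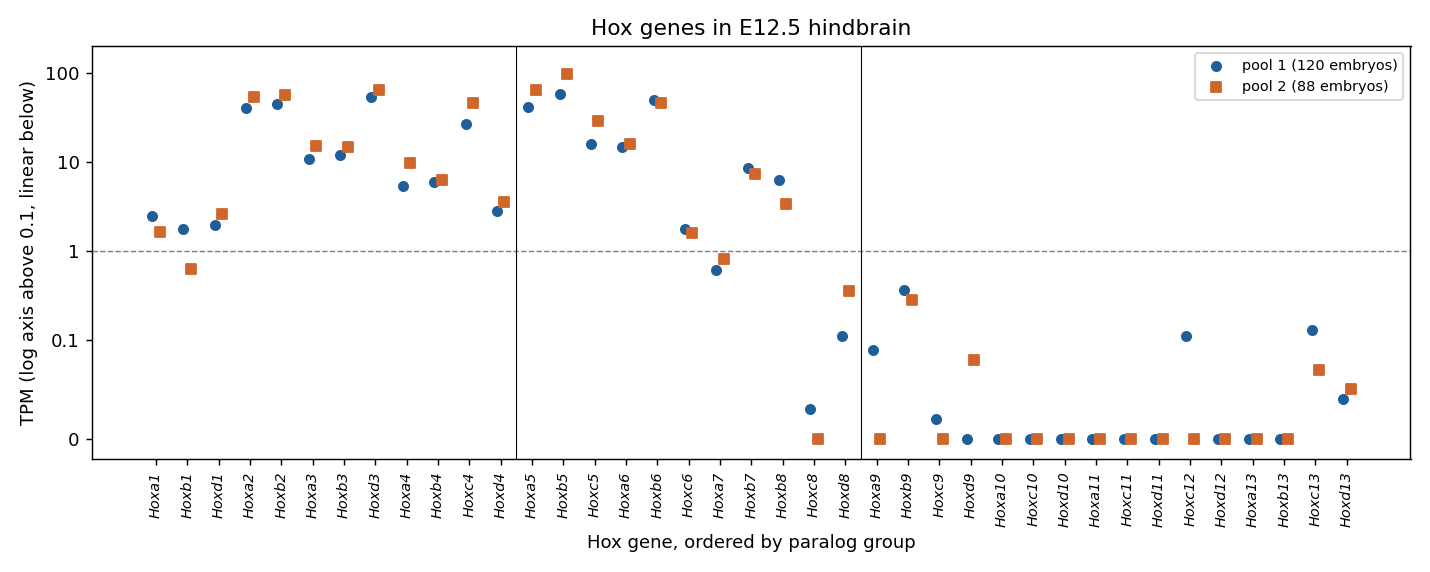
TPM of each Hox gene in pool 1 (circles) and pool 2 (squares), ordered along the horizontal axis by paralog group, with vertical lines after groups 4 and 8 and a dashed line at 1 TPM; the vertical axis is logarithmic above 0.1 TPM and linear below. In groups 1 to 4, 11 of 12 genes lie above the dashed line in both pools, in groups 5 to 8 it is 8 of 11, and in groups 9 to 13 it is 0 of 16.

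Genes of the isthmus, the organiser at the border of midbrain and hindbrain, and of the anterior hindbrain were expressed at higher levels than forebrain genes. Of this list 10 of 12 members reached 1 TPM in both pools, against 7 of 17 forebrain members and 2 of 6 midbrain members. Gbx2, which sets the anterior limit of the hindbrain, was at 42.2 ± 9.31 TPM, Pax8 at 25.5 ± 6.32 TPM, and Pax2 at 13 ± 1.82 TPM, whereas En2 stood at 0.585 ± 0.106 TPM. In the forebrain list, Emx1 (0.140 ± 0.0990 TPM), Six3 (0.435 ± 0.120 TPM) and Six6 (0.0800 ± 0.0707 TPM) were under 1 TPM in both pools. The highest forebrain members were Neurod6 (15.7 ± 2.47 TPM), Dlx5 (11.5 ± 4.57 TPM), Dlx1 (7.08 ± 0.926 TPM) and Dlx2 (3.88 ± 0.318 TPM), and Dlx genes are also expressed in the pharyngeal arches. Among midbrain genes, Otx2, which marks forebrain and midbrain and also the choroid plexus, was at 13.9 ± 2.37 TPM, Otx1 at 2.69 ± 0.148 TPM and Slc6a3, the dopamine transporter, at 0.0350 ± 0.00707 TPM.

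The isthmus and anterior hindbrain list exceeded the forebrain list by 2.61 ± 0.20 in mean log2(TPM + 0.1) (SD, n = 2 pools), with an adjusted p of 0.00944 in a two-sided permutation test across genes. The difference from the midbrain list was 2.06 ± 0.07 and was not past the threshold (exact permutation test, adjusted p = 0.0702). When members under 1 TPM in both pools were left out, the difference from the forebrain fell to 1.46 and was no longer past the threshold (permutation test, adjusted p = 0.157, range over the alternatives 0.00704 to 0.157). The midbrain count depended on the threshold, with 5 of 6 members at 0.5 TPM or more and 1 at 5 TPM or more.

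Progenitor and neuronal genes were both abundant. All 14 members of the radial glia and progenitor list reached 1 TPM in both pools, led by Fabp7, a fatty acid binding protein of radial glia (1166 ± 103 TPM), the intermediate filament gene Vim (797 ± 29.4 TPM), the Notch target Hes5 (240 ± 21.4 TPM) and Sox9 (152 ± 0.856 TPM). All 14 members of the cell cycle list did too, with Cdk1 at 166 ± 6.41 TPM and Top2a at 152 ± 3.27 TPM. All 14 members of the list of postmitotic neurons were also expressed, with the neuronal tubulin Tubb3 at 807 ± 8.65 TPM, the intermediate filament genes Ina (467 ± 26.6 TPM) and Nefl (399 ± 25.1 TPM), and Stmn3 at 388 ± 3.88 TPM. The list medians were 75.8 TPM for radial glia and progenitors, 99.9 TPM for the cell cycle and 268 TPM for neurons, at percentiles 99.99, 100 and 100 among random lists of the same size. Those random lists also held protein-coding genes that were not expressed. The housekeeping, erythroid and mitochondrial lists stood at percentile 100 too. Neurons exceeded radial glia and progenitors by 1.65 ± 0.14 in mean log2(TPM + 0.1), which was not past the threshold (permutation test, adjusted p = 0.0791, n = 14 genes in each list).

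Both the dorsal and the ventral progenitor domains were represented. Of the dorsal domain and rhombic lip list, 12 of 13 members reached 1 TPM in both pools (median 15.4 TPM). Among them were Msx1 (82.4 ± 11.7 TPM) and Msx2 (48.4 ± 2.41 TPM), targets of dorsal BMP signalling, and the proneural gene Neurog2 (35.7 ± 2.35 TPM). Msx1 and Msx2 were the highest of this list, and which cells of the dissection expressed them was not tested. Of the ventral domain and floor plate list, 10 of 11 reached it (median 3.64 TPM), with the axon guidance gene Ntn1 at 42.3 ± 4.49 TPM, Dbx1 at 18.8 ± 6.91 TPM, Nkx6-1 at 14.4 ± 0.368 TPM and Nkx6-2 at 14.3 ± 0.601 TPM. Nkx2-9 was under 1 TPM in both pools (0.660 ± 0.339 TPM). The 2 lists were not tested against each other.

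Transcription factors of hindbrain and cerebellar neuron classes were expressed in 18 of 20 cases, with Lhx1 (51.6 ± 1.73 TPM) and Lhx5 (50.2 ± 1.97 TPM), Pou4f1 (46.3 ± 7.43 TPM) and Foxp2 (36.6 ± 1.32 TPM) the highest, and Tbr1, a gene of glutamatergic cerebellar nuclear neurons, at 0.265 ± 0.219 TPM. The inhibitory transmitter genes were all above 1 TPM in both pools: Gad2 (42.1 ± 4.00 TPM) and Gad1 (19.0 ± 0.134 TPM), which synthesise GABA, the glycine transporter Slc6a5 (7 ± 0.926 TPM) and the vesicular transporter Slc32a1 (3.00 ± 0.389 TPM). Among the vesicular glutamate transporters, Slc17a6 was at 34.5 ± 3.33 TPM, Slc17a8 at 1.78 ± 0.311 TPM and Slc17a7 at 0.885 ± 0.106 TPM. Among motor neuron genes, Isl1 was at 34.6 ± 0.955 TPM and Isl2 at 14.2 ± 1.85 TPM, while Mnx1, a gene of somatic motor neurons, was at 0.370 ± 0.269 TPM. All 6 serotonergic and all 4 noradrenergic list members reached 1 TPM in both pools, including the serotonergic factor Fev (5.63 ± 0.354 TPM) and tyrosine hydroxylase, Th (11.6 ± 0.0707 TPM). The GABA and glycine list exceeded the glutamate list by 1.53 ± 0.21 in mean log2(TPM + 0.1), which was not past the threshold (exact permutation test across 4 and 3 genes, adjusted p = 0.442).

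Genes of mature glia were low beside those of radial glia. Gfap, the intermediate filament of mature astrocytes, was at 0.0650 ± 0.0354 TPM, and the myelin genes Mag and Mog were at 0.450 ± 0.0283 and 0.820 ± 0.226 TPM. Some members of the glial lists were nonetheless well expressed, such as the gap junction gene Gja1 (139 ± 15.8 TPM) of the astrocyte list, a gene also of radial glia, and Pdgfra (42.5 ± 5.16 TPM) of the oligodendrocyte list, a gene also of mesenchyme. Against radial glia, the difference in mean log2(TPM + 0.1) was -3.63 ± 0.02 for the astrocyte list (6 genes, exact permutation test, adjusted p = 0.0356) and -3.44 ± 0.05 for the oligodendrocyte list (7 genes, exact permutation test, adjusted p = 0.0252). Both calls ended when members under 1 TPM in both pools were left out, at -2.67 and -2.28 (exact permutation test, adjusted p = 0.157 for each; range over the alternatives 0.0347 to 0.157 for astrocytes and 0.0228 to 0.157 for oligodendrocytes). With log2(TPM + 1) the astrocyte difference was -3.02 (adjusted p = 0.0505).

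**Figure D2:**
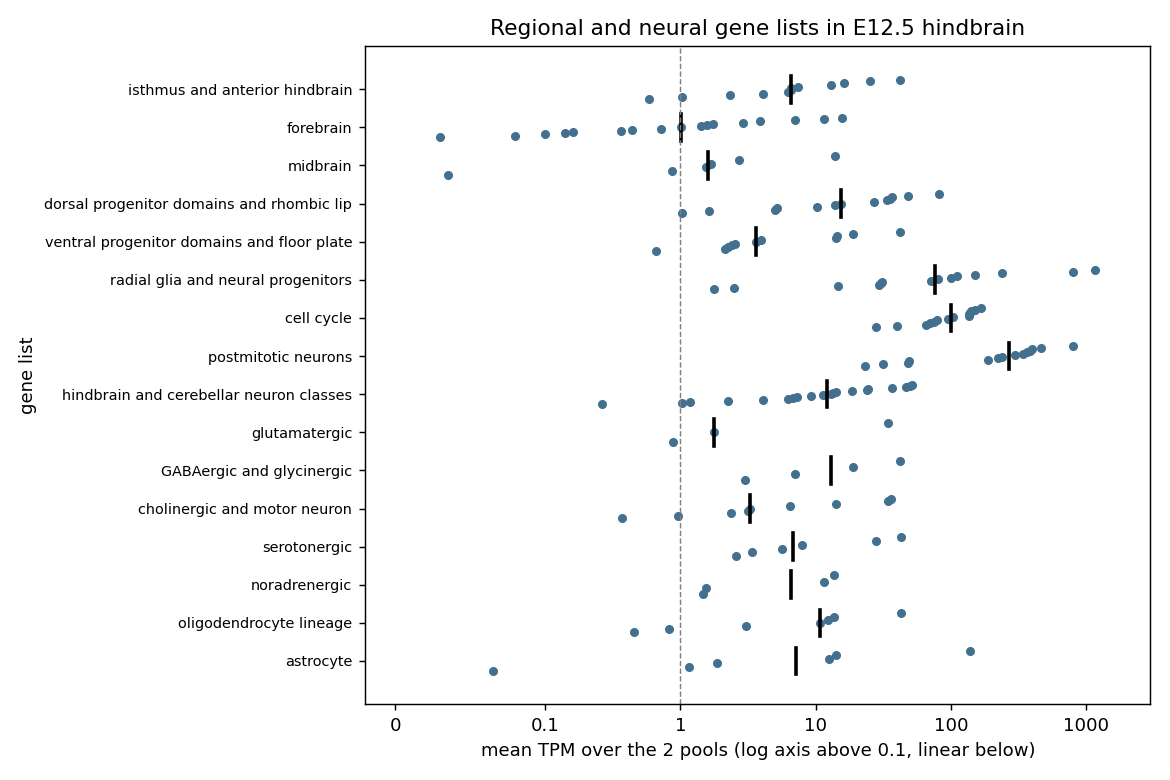
Mean TPM over the 2 pools of each member (points) of 16 regional, progenitor, neuronal and glial gene lists, with the list median as a vertical bar and a dashed line at 1 TPM; the horizontal axis is logarithmic above 0.1 TPM and linear below. Medians reach 268 TPM for postmitotic neurons and 75.8 TPM for radial glia, against 1.01 TPM for forebrain genes.

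Genes of blood, vessels, meninges and other tissues were also found. Erythroid genes had a median of 538 TPM, and the 7 globin genes took 0.597% ± 0.1 of the gene counts (SD, n = 2). Mesenchymal collagens were abundant, with Col3a1 at 490 ± 103 TPM and Col1a1 at 459 ± 93.7 TPM, as was the cartilage collagen Col2a1 at 364 ± 13.1 TPM. Choroid plexus was represented by Ttr (346 ± 41.8 TPM) and microglia by C1qb (25.6 ± 1.63 TPM) and C1qc (15.4 ± 0.226 TPM). Endothelium was represented by Cldn5 (25.1 ± 2.60 TPM) and Kdr (24.5 ± 0.163 TPM). Pdgfrb of the endothelium and pericyte list stood at 29.2 ± 1.17 TPM, and whether pericytes or other cells expressed it was not tested. Tmem119 had the highest mean of the microglia list (32.8 ± 1.47 TPM), but which cells expressed it was not tested. All 10 members of the microglia list and all 12 of the endothelium and pericyte list reached 1 TPM in both pools. All 8 members of the cranial ganglia and neural crest list (such as Prph at 22.7 ± 6.56 TPM) and all 6 of the surface epithelium list (Epcam at 29.1 ± 13.7 TPM) did so as well. Of the immediate early and heat shock genes, Jun was at 60.4 ± 7.99 TPM and Fosb at 0.0550 ± 0.0354 TPM. Both Xist (20.8 ± 2.82 TPM) and the Y-linked gene Eif2s3y (33.5 ± 5.30 TPM) were present, as the labels give both pools as mixed in sex.

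Genes of skeletal muscle were higher in pool 2. Among genes with a mean of 10 TPM or more and 50 or more mean counts, the 6 with the largest ratio in that direction all encode sarcomere proteins: Tnnc2 (3.82 and 24.0 TPM in pools 1 and 2, 6.18-fold), Myh3 (3.35 and 20.1 TPM, 5.94-fold), Myl1 (5.09-fold), Actn2 (5.02-fold), Acta1 (4.72-fold) and Tnnc1 (4.61-fold). Myh3, embryonic myosin heavy chain, is ENSMUSG00000020908.14 on chromosome 11 of mm10 (positions 67078300 to 67102291, plus strand). In the fixed list of cartilage and skeletal muscle, 10 of 10 members were higher in pool 2 (median log2 ratio 2.06). Its 6 muscle members, taken apart after the values were seen, had a median log2 ratio of 2.20, and the muscle regulator Myog was 4.60-fold higher in pool 2. Of its 4 cartilage members, the proteoglycan and matrix genes Matn1 (4.12-fold) and Acan (2.66-fold), named after their values were seen, were also higher in pool 2, while the collagens Col2a1 and Col9a1 had log2 ratios of 0.07 and 0.11.

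Within the same limits of 10 TPM and 50 mean counts, the 6 genes with the largest ratio towards pool 1 were the retinoic acid synthesising enzyme Aldh1a3 (17.2 and 5.78 TPM in pools 1 and 2, 3.03-fold), Crym (2.46-fold), the tight junction gene Cldn6 (2.45-fold), the neutrophil calcium-binding protein S100a8 (2.38-fold) and 2 processed pseudogenes, Gm10146 and Gm43110, whose reads can be shared with their parent genes. Aldh1a3 is ENSMUSG00000015134.15 on chromosome 7 of mm10 (positions 66390890 to 66427517, minus strand). The surface epithelium list was lower in pool 2 (median log2 ratio -0.48), with Epcam 2.01-fold, Krt8 1.58-fold and Krt18 1.54-fold higher in pool 1. Its other members went both ways: Krt5 had a log2 ratio of 0.21, Krt14 of -0.33 and Krt15 of 0.70 (the last 2 named after their values were seen). All 7 globin genes were higher in pool 1 (median log2 ratio -0.33), as were 12 of 13 mitochondrial genes (median -0.21).

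Across the 31 fixed lists, the median shift of 16 lay outside the central 95% of expression-matched random lists, 10 towards pool 2 and 6 towards pool 1. Towards pool 2 these were forebrain (0.74), Hox groups 1 to 4 (0.34), meninges and mesenchyme (0.27), isthmus and anterior hindbrain (0.27), cholinergic and motor neurons (0.24), cranial ganglia and neural crest (0.24), GABA and glycine (0.19), oligodendrocyte lineage (0.19) and postmitotic neurons (0.10), beside the muscle list. The cholinergic shift fell to 0.15 and inside the central 95% with members of 50 or more mean counts, and the oligodendrocyte shift fell inside it with M4 (0.19). In the oligodendrocyte list, Sox10 (-0.69) and Olig1 (-0.95, named after its value was seen) went towards pool 1. Towards pool 1 they were serotonergic (-0.29), erythroid (-0.28), radial glia (-0.14) and cell cycle (-0.09) genes, beside the surface epithelium and mitochondrial lists. Among Hox genes, Hoxa4 (0.82), Hoxc4 (0.76), Hoxb5 (0.73), Hoxc5 (0.67) and Hoxa5 (0.61) had higher levels in pool 2, whereas Hoxb8 (-0.81) and Hoxb1 (-1.28) had lower ones. The housekeeping list had a median log2 ratio of 0.00 to 2 decimals (percentile 32.7). The percentiles describe these 2 libraries and treat genes as independent, so that co-regulated lists reach the extremes with small shifts. Scaling to the spike-ins moved the median of all compared genes by -0.37 on the log2 scale; the shifts above are relative to that median, and those towards pool 2 that were smaller than it turned negative in absolute terms.

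In all, 149 of 14989 genes with 50 or more mean counts differed 2-fold or more between the pools, 87 towards pool 2 and 62 towards pool 1, and no test can be made with 2 libraries. Over the 16100 genes at 1 TPM or more in both pools, log2(TPM + 0.1) correlated between the pools at r = 0.991. Genes are not independent replicates, and genes low in either pool were left out of this value. The biological coefficient of variation was 0.0858 (edgeR). This value is the spread between 2 pools of 120 and 88 embryos, and it does not measure variation between single embryos. The counts of the pools differed by more than sampling noise (chi-square 8.59 per degree of freedom over 19388 genes), which shows no more than that the tables do not hold copies of the same library. The 2-fold count depended on the count minimum and the scaling: it was 779 with 10 or more mean counts, 38 with 200 or more, and 255 with spike-in scaling, of which 51 were higher in pool 2 and 204 in pool 1.

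**Figure D3:**
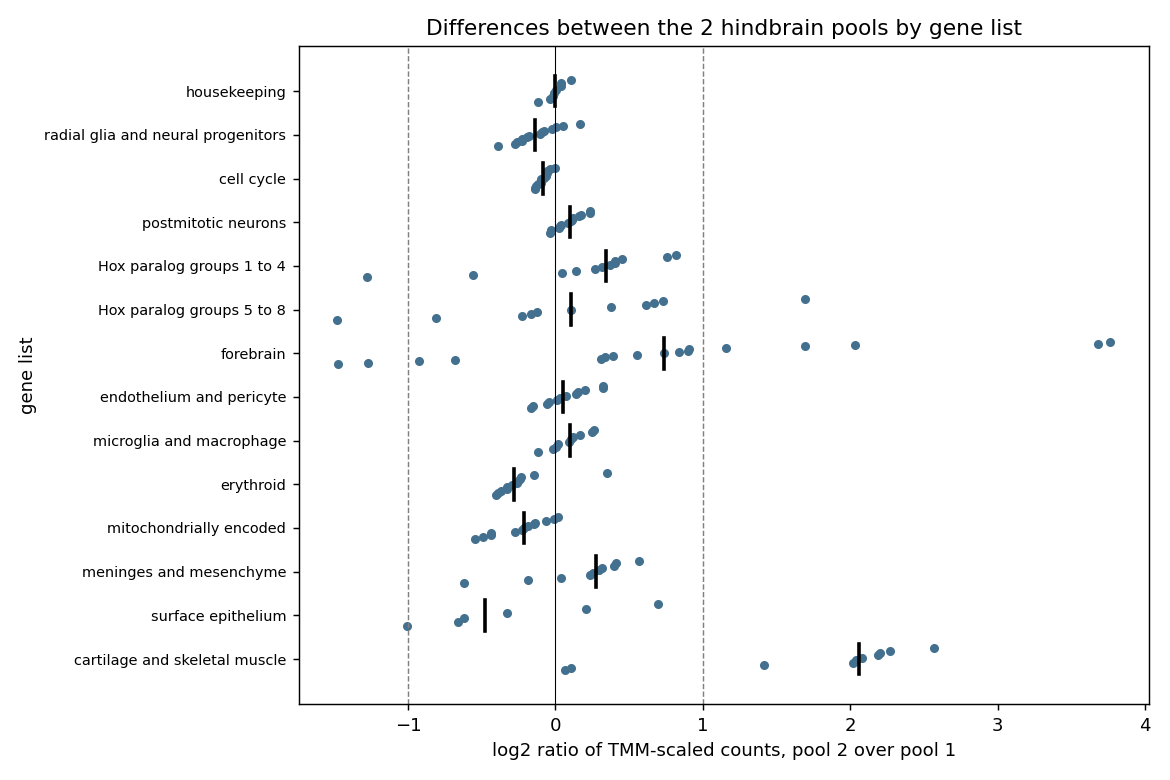
Log2 ratio of scaled counts, pool 2 over pool 1, of each member with any count (points) of 14 gene lists, with the list median as a vertical bar and dashed lines at a 2-fold difference. The muscle members lie near 2 and above, the cartilage and muscle list median is 2.06, the surface epithelium median is -0.48 and the housekeeping genes lie close to 0; spike-in scaling would move every point by -0.37.

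Several neuronal and progenitor genes were represented by more than 1 isoform. The 5 genes named here were Vim, Map2, Elavl4, Dcx and Prom1. For Vim, the entry Vim-203, annotated as a retained intron, held 35.5% ± 0.192 of the gene's TPM (SD, n = 2) and the coding Vim-206 held 32.8% ± 0.198. For Dcx, a microtubule protein of migrating neurons, Dcx-203 held 50.5% ± 3.74 and Dcx-201 held 32.7% ± 3.99. For the neuronal microtubule gene Map2, Map2-201 held 38.9% ± 3.85 among 13 isoforms at 1 TPM or more, and for Prom1 the leading isoform Prom1-203 held 26.8% ± 2.83. For the RNA-binding protein gene Elavl4, Elavl4-211, annotated as a processed transcript, held 29.6% ± 3.30 and the coding Elavl4-202 held 25.7% ± 1.86. Across the transcriptome 8829 genes had 2 or more isoforms at 1 TPM or more in both pools, or 4267 at 5 TPM. Of 8861 genes at 10 TPM or more with several annotated isoforms, the top isoform was the same in both pools in 8266, and its median share was 65.8%. Shares of isoforms with common exons are estimates that divide shared reads.

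Between GENCODE M21 and the older M4, the same reads gave TPM values that differed 2-fold or more in both pools for 490 of 16062 genes, 316 higher with M21 and 174 higher with M4. Of the genes in the fixed lists, 83 moved by more than the SD between the pools with M4 and 228 did not. Dbx2, a gene of ventral progenitors, was the 1 list gene that differed 2-fold or more, at 2.12 ± 0.983 TPM with M21 and 0.745 ± 0.346 TPM with M4. The pseudogenes Gm6361 (95.9 ± 1.39 TPM), Gm10774 (65.6 ± 8.48 TPM) and Gm5537 (13.8 ± 3.81 TPM) were listed at 0 in M4. Platr25 (25.5 ± 0.382 against 0.365 ± 0.00707 TPM) and the histone gene Hist1h2br (11.4 ± 0.523 against 0.180 ± 0.255 TPM) were also higher with M21. Higher with M4 were Gm6565 (98.6 ± 1.36 TPM), Gm49342 (31.4 ± 0.870 TPM) and Gm45837 (18.5 ± 0.354 TPM), each at 0 with M21, Gm7292 (123 ± 1.82 against 0.365 ± 0.00707 TPM) and the nucleoporin gene Nupl1 (43.6 ± 3.31 against 0.0250 ± 0.0354 TPM). Several of these are pseudogenes or overlapping models, so the division of reads between them and related genes is uncertain. Genes were matched between the annotations by identifier without its version, and M4 genes were given M21 symbols. An identifier whose gene model or name changed can therefore appear here as a difference in the same gene.

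Spike-in RNAs took a larger share of the library in pool 2. They held 3.31% of the expected counts in pool 1 and 4.25% in pool 2 (mean 3.78% ± 0.661, SD, n = 2), or 7.97% and 10.3% of the TPM. Over the 62 spike-ins with 10 or more counts in both pools, the median log2 ratio of counts was 0.23, and across these spike-ins, which are not independent samples, the log2 counts of the pools correlated at r = 0.998.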

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

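These values come from data outside the main comparisons, and their origin was not tested. The 26248 tRNA entries of the tables held 33.69 expected counts in pool 1 and 34 in pool 2. The total was noted because it is not 0, and it says nothing of any single tRNA entry. In addition, 108 genes found in the M4 annotation, with no counterpart of the same identifier in M21, reached 1 TPM or more in both pools, and the 884 genes of this kind took 0.284% of the M4 gene counts in pool 1 and 0.281% in pool 2.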

How the results depend on the processing

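Hox groups 5 to 8 exceeded groups 9 to 13 under each alternative that gave a value (3.06 to 5.59, with adjusted p = 8e-05 in each permutation test); leaving out members under 1 TPM in both pools gave none, since no member of groups 9 to 13 was left. That same filter gave -0.71 for Hox groups 1 to 4 against 5 to 8, 1.46 for isthmus against forebrain, -2.67 for astrocytes against radial glia and -2.28 for oligodendrocytes against radial glia, with fewer genes in the lists and adjustment over 7 pairs. With log2(TPM + 1) the astrocyte difference was -3.02, and the cause was not tested. The midbrain count was 4 with posterior means, 5 at 0.5 TPM and 1 at 5 TPM, and the forebrain count 3 at 5 TPM. Genes differing 2-fold between the pools numbered 255 with spike-in scaling (51 towards pool 2, 204 towards pool 1), 779 with 10 or more mean counts (388 and 391) and 38 with 200 or more (26 and 12); the share differing 2-fold was 14.3% of genes with 10 to 50 mean counts and 0.104% of those with 1000 to 10000. The annotations differed for 296 genes at 10 TPM and 136 at 4-fold, and 4267 genes had several isoforms at 5 TPM. Each pool alone gave 16842 to 16892 genes at 1 TPM, 264 to 266 list members, 569 to 592 genes between annotations, 9495 to 9535 genes with several isoforms and a spike-in share of 3.31% to 4.25%. Among single list genes, the TPM of 83 moved by more than the SD between the pools with M4, of 84 with posterior means and of 135 when TPM was rescaled without spike-ins, which multiplies all genes of a pool by 1 factor and was chosen after seeing the data. The coefficient of variation ran from 0.0842 to 0.0902. Where no cause is given, the cause was not tested. Of the list shifts, oligodendrocyte genes with M4 (0.19) and cholinergic genes with 50 or more counts (0.15) fell inside the central 95%.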

Other observations

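The tests on scaling and on dividing cells were chosen after their results were seen, and the 4 added lists were chosen after the fixed lists had been seen but before the values of their own members were examined. The labels give no difference between the pools except the number of embryos, so no biological explanation from the design was tested. Among genes outside the fixed lists, those of the otic epithelium, which forms the inner ear beside the hindbrain, had a lower median in pool 2. Fbxo2 was at 8.46 TPM in pool 1 and 2.56 TPM in pool 2, the otoconial gene Otol1 at 3.08 and 0.680 TPM, Otog, an acellular membrane gene, at 3.52 and 1.06 TPM and Otoa at 1.76 and 0.430 TPM, while Hmx2, which is also a neuronal gene, was at 2.73 and 3.03 TPM. Muscle genes outside the fixed lists were higher in pool 2, such as Neb (2.53 and 15.1 TPM), Mybph (1.83 and 12.2 TPM) and Des (1.81 and 8.03 TPM). The acetylcholine receptor gene Chrng of embryonic muscle was at 0.700 and 2.34 TPM.

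The muscle genes higher in pool 2 are not accounted for by scaling or library size, since their median log2 ratio exceeded that of the housekeeping list by 2.2. A candidate explanation is more skeletal muscle tissue in the pool 2 dissection: of the unseen muscle genes with 10 or more mean counts, 18 of 18 were higher in pool 2, with a median log2 ratio of 1.691. Muscle genes were also present in pool 1, at 6.06 TPM for Myog and 7.58 TPM for Acta1. Of the cartilage genes in the fixed list, Matn1 (2.04) and Acan (1.41) had high ratios too and Col2a1 (0.07) and Col9a1 (0.11) did not, and whether cartilage tissue differed between the pools was not tested.

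More surface epidermis was considered for the otic and epithelial genes higher in pool 1 (Epcam, Krt8, Krt18, Cldn6). Unseen genes of surface epidermis had a median log2 ratio of -0.01. Of these 7 genes, 2 were higher in pool 2 and 5 in pool 1, and Perp was at 9.16 and 9.17 TPM. The median argues against surface epidermis as the main source, but 7 genes in 2 libraries cannot exclude a part. More otic epithelium in the pool 1 dissection is a candidate explanation, since the unseen otic genes had a median log2 ratio of -1.414 and 10 of 10 had a ratio of scaled counts below 0. For Hmx2 that ratio was -0.01, with a TPM slightly higher in pool 2. The levels of these genes were low, and other epithelia were not tested. Gata3 and Gata2 of the serotonergic list, which were lower in pool 2 (-0.49 and -0.39), are also expressed in the otic epithelium. Of the other members of that list, Tph2 (-0.46), Fev (-0.19) and Slc6a4 (-0.02) were lower too and Ddc (0.44) was higher. Whether otic epithelium contributed to the serotonergic shift was not tested.

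Some abundant RNAs without a poly(A) tail were lower in pool 2: the log2 ratio was -0.48 for Rn7s1 and -0.44 for the ribosomal RNA entry CT010467.1, and 50 of 60 replication-dependent histone genes were lower (median -0.35), though histone genes share reads. The cell cycle list was lower by less (median -0.087), with 14 of 14 members lower in pool 2. That comparison was chosen after its result was seen, so fewer dividing cells are not excluded. Whether less carryover of such RNA in library 2 may account for the lower levels cannot be told apart from other explanations. The 2 unseen RNAs of this kind with 10 or more mean counts went opposite ways (median 0.088). The class as a whole is therefore not shown to be lower.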
